A study of Rattus norvegicus with 6 samples.

How the data were processed

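Kidneys of Dahl salt-sensitive rats were assayed by ATAC-seq in 6 libraries, 3 from animals given 1,3-butanediol and 3 from untreated animals, grouped by the treatment label. Sex, batch and litter were given for no library. Per the labels' protocols, flash-frozen kidney was pulverised, nuclei were isolated from 100 mg of powder and enriched on a density gradient, 50000 nuclei were tagmented by the Omni-ATAC procedure, and libraries were sequenced in paired-end reads of 150 bases. Per the submitters' processing notes, FastQC, Trim Galore and cutadapt were used and the build was rn6. The aligner, the peak caller and its thresholds, any shift of reads for the transposase, and the rule by which peaks were merged are not given in the sources used here.

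The authors deposited 1 list of merged regions with 4 columns and no header, namely chromosome, start, end and a running name. The positions are the only measurement. They were read as 0-based starts, as in the BED format, and are reported 1-based. The regions were sorted by chromosome and start before use and were found free of overlaps, and the list names no library or group. Peaks were therefore treated as a pooled catalogue. Whether the authors called peaks per library before merging is not given in the sources used here. Read depth per library was unknown, so no counting interval or detection limit is given.

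A comparison of the groups, the placement of regions relative to genes, tests of gene lists (nephron segments, stromal and immune cells, ketone and fatty acid metabolism, blood pressure genes, inflammation, fibrosis and control tissues) and tests of transcription factor motifs had been planned before the data were examined, for the case that the files allowed them. None was run. The group comparison needs a value per library or a group of origin, and the others need an rn6 annotation or sequence. The gene table used for reference was of the GRCr8 build, without sequence. On 15 of the 22 chromosomes the list has regions beyond the last gene of that table, and no position was carried over between builds. Named positions follow the rule set beforehand for the 10 widest regions. Dense windows, long gaps, runs and regions of the sex chromosomes were chosen after their values were seen. Of what is reported, only the catalogue of regions, their widths and their distribution over chromosomes had been set beforehand. The tests of the X, windows, spacing, wide regions and gaps were chosen after the list had been seen.

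Widths, gaps and densities were computed in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. The density of a chromosome was the number of regions over the span from its first to its last region, since chromosome lengths were not used. Windows were 1 Mb long, regions were assigned by midpoint, and the incomplete windows at the ends of a span were left out. The variance to mean ratio was computed around the mean of each chromosome and pooled over the 20 autosomes. Random lists kept the number and widths of the regions of each chromosome and placed them without overlap, 1000 times over the span and 200 times within the window of each region. Joined regions were placed within windows both freely and at least 500 bp apart. The X was compared with the autosomes by an exact permutation test over the 21 chromosomes, with Benjamini-Hochberg adjustment over 8 measures. Wide regions, of 1 kb or more, were compared with the others by 1000 permutations of widths within chromosomes. Gaps were sorted by the wider of their 2 flanking regions, and the ratio of the counts in a pair of neighbouring length classes was given a 95% interval from Poisson counts, which covers counting error only, and was also compared with 200 permutations of widths. Chromosomes, windows and regions are not replicates, so these tests describe this list and not a population of rats.

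The statistics were tested on simulated data. A simulated list with a variance to mean ratio of 21 gave 21.8, a list with the X thinned to 0.3 of the autosomal density gave 0.304, and a list in which 40% of regions had a neighbour within 1 kb gave 40%. A uniform list gave a ratio of 0.942, slightly below 1 because regions cannot overlap. For the quotient of the changes in gap counts beside wide and between narrow regions, 40 uniform lists averaged 1.02 and ranged from 0.913 to 1.21, and the interval held 1 in 39 of them. Removing 50% of the narrower neighbours within 4500 bp of wide regions from a uniform list gave 1.96 (95% interval 1.74 to 2.20). That limit was also the bound between the gap classes, so this case was built to exceed 1 and does not represent a gradual rise. Alternatives used regions of at least 300 bp alone and regions less than 500 bp apart joined. Added after seeing the data were windows of 500 kb and 2 Mb, neighbour distances of 500 bp and 2 kb, the list without regions of exactly 200 bp, placement within windows, and all settings of the gap step.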

Results

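Chromatin accessibility was profiled by ATAC-seq in the kidneys of Dahl salt-sensitive (SS/Jr) rats, an inbred strain that develops hypertension and kidney injury when fed salt. ATAC-seq inserts sequencing adapters with a transposase wherever DNA is not covered by nucleosomes, so a peak marks an open stretch such as an active promoter or enhancer. The 6 libraries fell into 2 groups of 3. One group received 1,3-butanediol, an alcohol that the liver converts to the ketone body β-hydroxybutyrate, at 20% in the drinking water. The series describes 6 weeks of supplementation, and the other group was untreated. The question behind the design was whether raised β-hydroxybutyrate, which also modifies histones, went with altered chromatin occupancy in the kidney.

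The data consisted of a single list of accessible regions. Its name describes it as the merged peaks of HMB against HMC. These codes were read here as the butanediol and untreated sets, and no column of the list bears on this. Each region carried a chromosome, a start, an end and a running name. The list held no read count, score, fold change or group of origin, so the depth of each library was unknown, and accessibility in butanediol-treated kidneys was not compared with that in untreated kidneys here. No region below is attributed to either group. The values describe 1 pooled list without replicates, so no error between animals can be given. The comparisons of the X, of windows, of spacing and of wide regions were chosen after the list had been seen, and their p-values describe this list. Positions are in the rn6 build, 1-based, and overlap with genes was not analysed here, because no rn6 annotation was used.

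The merged kidney list held 151302 accessible regions on the 20 autosomes, the X and the Y chromosome. Together they covered 75.1 Mb, or 2.71% of the 2776 Mb between the first and the last region of each chromosome. The median region was 398 bp wide (interquartile range 285 to 604 bp) and the mean was 497 ± 304 bp (SD over regions). No 2 regions overlapped. Regions of 1 kb or more numbered 11768, which was 7.78% of the list and 20.1% of the covered bases. Only 233 regions reached 2 kb.

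The widest region was at chr1:189469396-189472789, 3394 bp long. It was followed by chr8:49720945-49723939 with 2995 bp, chr10:56010378-56013319 with 2942 bp and chr12:36644139-36646995 with 2857 bp. Chromosome 7 held a region of 2795 bp at 78090398-78093192 and another of 2649 bp at 51232049-51234697. The list of the 10 widest was completed by chr15:28015184-28017971 (2788 bp), chr10:57274686-57277378 (2693 bp), chr9:50556726-50559370 (2645 bp) and chr1:229392625-229395259 (2635 bp). None of the 10 was on a sex chromosome, and the widest region of the X, at 10412905-10415124, was 2220 bp long.

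**Figure D1:**
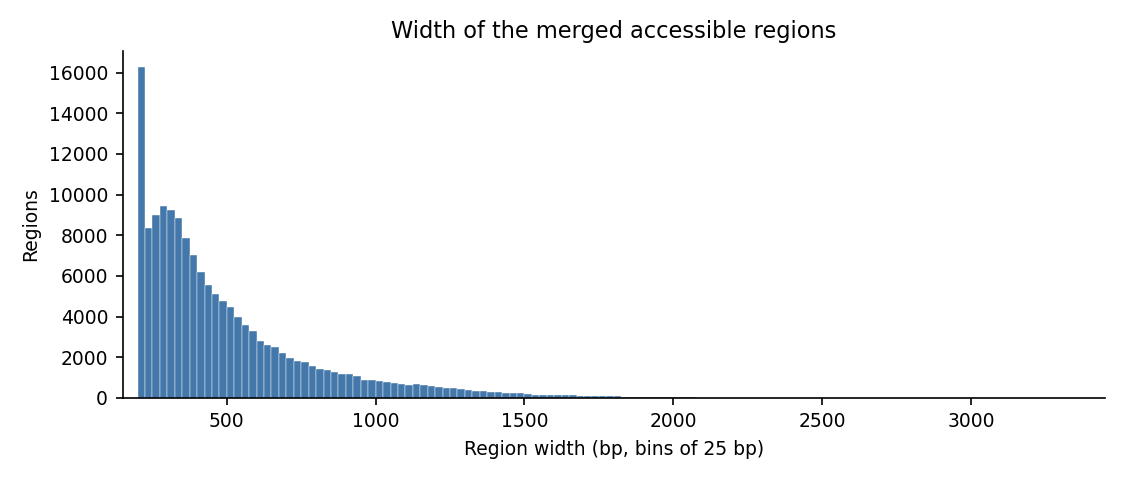
Number of accessible regions (y axis) by width in bins of 25 bp (x axis, bp) over the whole pooled list. No region was narrower than 200 bp, the first bin includes the 7000 regions of exactly 200 bp, and the widest region was 3394 bp.

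Accessible regions were unevenly shared between the autosomes. Density, taken over the span from the first to the last region, averaged 58.6 ± 10.6 regions per Mb (SD over 20 autosomes). Chromosome 10 was the densest with 85.0 regions per Mb, followed by chromosome 12 with 74.2, chromosome 20 with 72.3 and chromosome 19 with 71.3. Chromosome 2 was the sparsest with 44.3 regions per Mb, and chromosome 11 had 47.2. The highest density was 1.92 times the lowest. Covered bases followed the same extremes, with 4.36% of the span on chromosome 10 and 2.15% on chromosome 2. Median width differed little between autosomes, from 387 bp on chromosome 9 to 414 bp on chromosome 10.

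The X chromosome held 2580 regions, or 16.1 per Mb, which was 0.276 times the autosomal mean and below chromosome 2, the lowest autosome. The X had the lowest density of the 21 chromosomes other than the Y (two-sided exact permutation test over which chromosome is taken as the X, p = 0.048, the smallest this test allows). Over the 8 measures tested in this way the Benjamini-Hochberg adjusted value was 0.063, so the X did not pass 0.05 after adjustment in this exact test. A measure could pass only if all 8 reached the smallest p this test allows, and not all did. The adjusted value therefore says little about the size of the difference. In 158 whole 1-Mb windows the X averaged 16.0 ± 17.6 regions (SD over windows). None of the 292 runs of 158 consecutive windows on the 5 autosomes long enough to hold one averaged as little, and the lowest of these runs averaged 38.4. These runs overlap, and neighbouring ones share all but their end windows, so they are not independent comparisons. Regions of 1 kb or more were likewise fewer, with 1.38 per Mb on the X against 4.59 ± 1.20 per Mb on the autosomes (SD, 20 autosomes). Median width on the X was 371 bp, below the lowest autosomal value of 387 bp (exact permutation p = 0.048, adjusted 0.063).

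The Y chromosome carried 21 regions, 0.0139% of the list, between positions 66127 and 2842662. Their median width was 636 bp, and 4 of them were 1 kb or wider. The widest Y region, at 1237032-1238659, was 1628 bp long, and the next, at 92145-93527, was 1383 bp. Both sexes were used per the series, and the labels give the sex of no library.

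**Figure D2:**
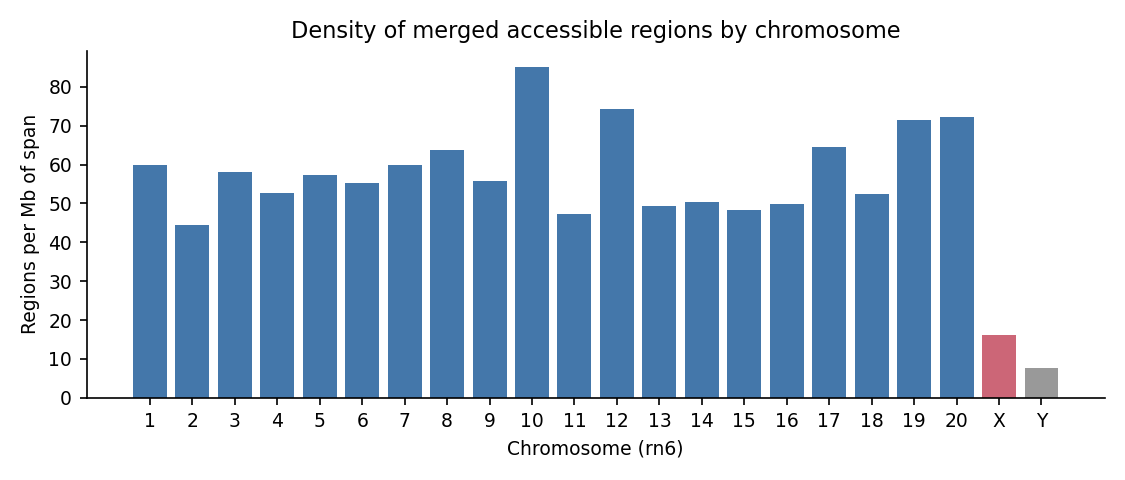
Accessible regions per Mb of the span between the first and last region (y axis) for each chromosome of the rn6 build (x axis), with autosomes in blue, the X in red and the Y in grey. The X bar, at 16.1, is below every autosome, and chromosome 10 is the highest at 85.0.

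The number of accessible regions varied widely between megabase windows. The 2587 whole autosomal windows held a median of 50 regions (interquartile range 17 to 88.5), with a maximum of 224, and 49 windows held none. The densest window was chr7:12000001-13000000 with 224 regions covering 12.4% of its bases, and the adjoining window chr7:11000001-12000000 held 214 regions. Next came chr3:164000001-165000000 with 187 regions, and chr1:266000001-267000000 and chr3:11000001-12000000 with 183 each. These windows were picked after their counts were seen. On the X the densest window, 11000001-12000000, held 85 regions. The variance of the autosomal counts was 33.7 times their mean, while 1000 placements of the same regions at random positions on their own chromosomes gave 0.857 to 1.04 (permutation test of positions, one-sided p = 0.000999, the smallest 1000 placements can give). Random positions could fall in unsequenced or repetitive stretches where reads cannot be placed, which were not masked.

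The longest stretch without a region was chr7:3791803-9458367, 5.67 Mb long. The X held the next longest stretches, 4.50 Mb at 87145989-91648124 and 3.55 Mb at 56770513-60318490. Chromosome 4 had a stretch of 2.43 Mb at 101361054-103789662. Of the 124 stretches longer than 1 Mb, 18 were on the X, where they made up 20.0% of the span, against 5.76% on the autosomes.

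**Figure D3:**
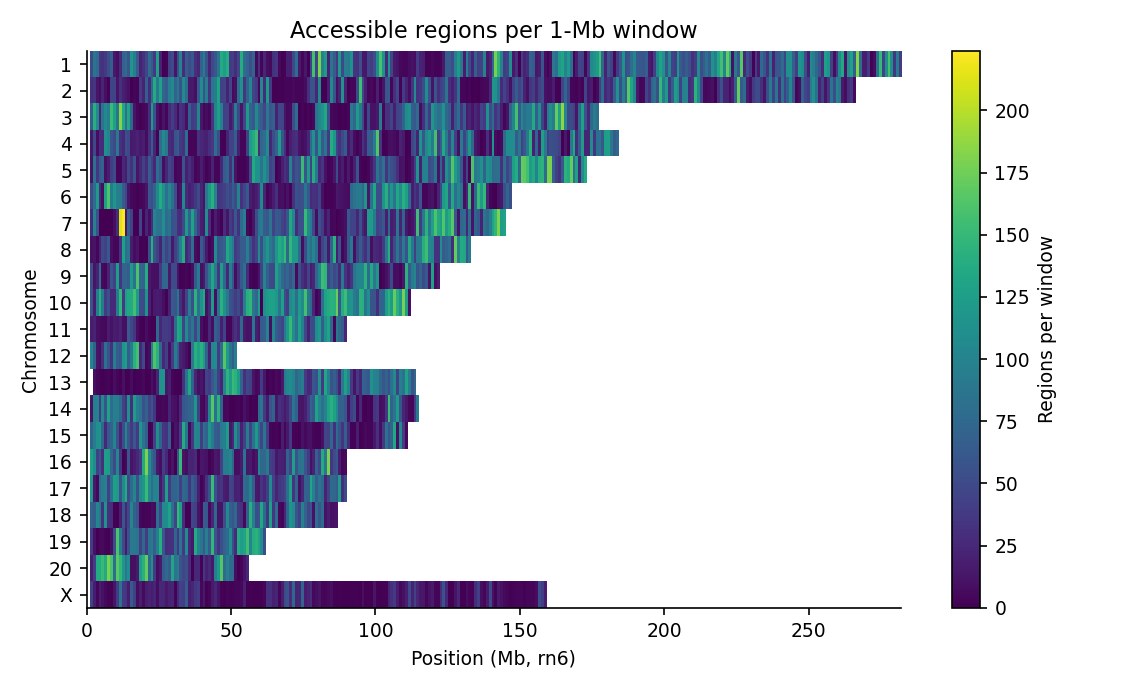
Number of accessible regions in each whole 1-Mb window (colour scale) along the autosomes and the X (rows), by position in Mb of the rn6 build (x axis); blank cells lie outside the span of a chromosome. The brightest windows, with 224 and 214 regions, are near the start of chromosome 7, and the X row does not exceed 85.

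Regions also lay close together at short range. The median gap between neighbours was 5637 bp, edge to edge, and the interquartile range was 1825 to 13054 bp. On the autosomes 32.1% of regions had another region within 1 kb. Random placement on the same chromosome gave 10.97% to 11.66% (permutation test of positions, one-sided p = 0.000999, the smallest possible). The share was 1.87 times the mean of 17.2% found when each region was placed at random within its own 1-Mb window, where 200 placements ranged from 16.9% to 17.5%. Joining regions less than 500 bp apart, which removes the closest neighbours, lowered the share to 13.1%. This was above the 8.08% to 8.63% found when the joined regions were placed within their own windows at least 500 bp apart, as joined regions are. It was below the 14.8% to 15.5% of placements within windows that also allowed shorter gaps.

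Runs of at least 2 regions, each less than 500 bp from the next, numbered 15374 and took in 33023 regions, 21.8% of the list. Runs of 4 or more were rare, at 251. The longest runs held 6 regions each, among them chr10:71158007-71162179 and chr15:34142316-34146416. Gaps of 1 to 40 bp were fewer, at 925, than gaps of 41 to 80 bp (2247) or 81 to 120 bp (2356), and the count declined to 1656 at 161 to 200 bp.

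At the median, regions of 1 kb or more lay farther from their nearest neighbour than narrower ones. Their median distance to the nearest region was 4566 bp against 2293 bp for narrower regions, 1.99 times as far, and permuting widths within chromosomes gave 2257 to 2544 bp (permutation test, two-sided p = 0.000999, the smallest possible). Wide regions were farther from their neighbours on 21 of the 21 chromosomes compared, the Y not included. They nonetheless lay in richer surroundings, with a mean of 95.7 regions in their own 1-Mb window against 90.0 for narrower regions, again on 21 of 21 chromosomes. Permuting widths gave 89.9 to 92.1 (permutation test, two-sided p = 0.000999). Widths were permuted region by region, although regions of the same window share its count, so this range may be too narrow. At the shortest range the difference was small, since gaps under 250 bp made up 6.51% of the gaps beside wide regions, 7.11% of those between regions both narrower than the median width and 7.56% of the rest. At 1000 to 1249 bp the shares were 1.46%, 2.80% and 2.60%. The X showed the same order of medians at longer range, with medians of 7352 bp for wide and 3923 bp for narrower regions.

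The count of gaps stepped up near 5 kb, except between narrow regions, where its decline only slowed. Over all gaps it went from 8991 at 3500 to 4499 bp to 10483 at 4500 to 5499 bp, 1.17 times as many (95% interval 1.13 to 1.20). Beside a region of 1 kb or more, 874 gaps measured 2500 to 3499 bp, 1169 measured 3500 to 4499 bp and 1933 measured 4500 to 5499 bp, and the count then declined to 1654 at 5500 to 6499 bp. Between regions both narrower than the median width, the counts declined over the same classes, with 2598, 2255, 2109 and 1696 gaps. Beside wide regions the rise was gradual and began before 4500 bp, with 225 gaps at 3500 to 3749 bp and 378 at 4250 to 4499 bp. The remaining gaps, whose wider flank was between the median width and 1 kb, went from 5567 to 6441, or 1.16 times (95% interval 1.12 to 1.20). From 3500 to 4499 bp to 4500 to 5499 bp the count changed 1.65 times beside wide regions (95% interval 1.54 to 1.78) and 0.935 times between narrow ones (0.881 to 0.992). These intervals cover counting error only. The quotient of 1.65 and 0.935 was 1.77 (95% interval 1.61 to 1.94), while 200 permutations of widths within chromosomes gave 0.850 to 1.13 (permutation test, one-sided p = 0.00498, the smallest possible). The bounds of these classes were set after the counts of all gaps had been seen.

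**Figure D4:**
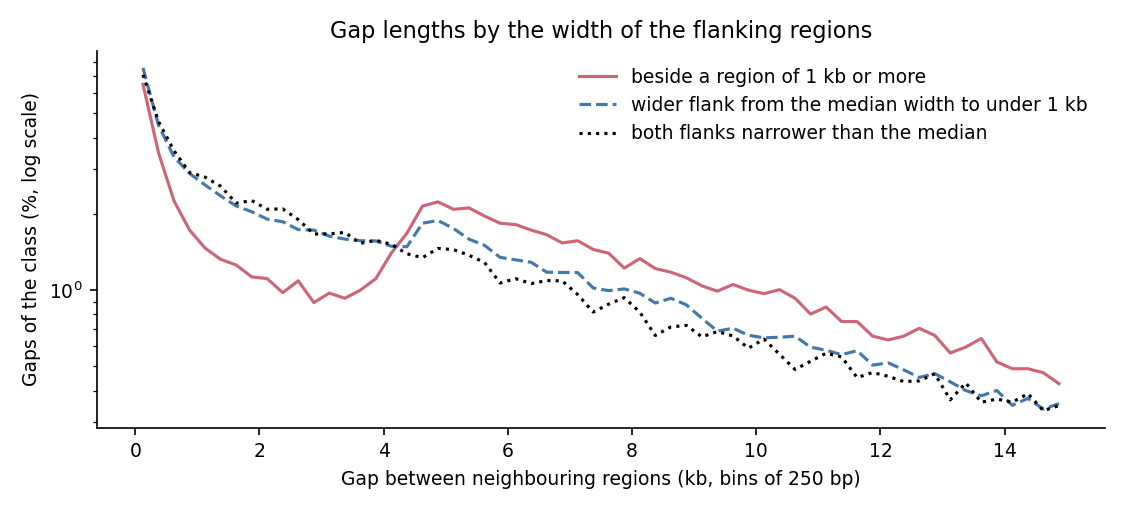
Percentage of the gaps of each class (y axis, log scale) by gap length in bins of 250 bp (x axis, kb) for gaps beside a region of 1 kb or more (red), between regions both narrower than the median (black, dotted) and for the remaining gaps (blue, dashed). The red curve rises from 225 gaps at 3500 to 3749 bp to 503 at 4750 to 4999 bp and then declines, the blue curve has a smaller rise, from 1353 at 4250 to 4499 bp to 1718 at 4750 to 4999 bp, and the black curve has a slight bump within a decline.

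**Figure D5:**
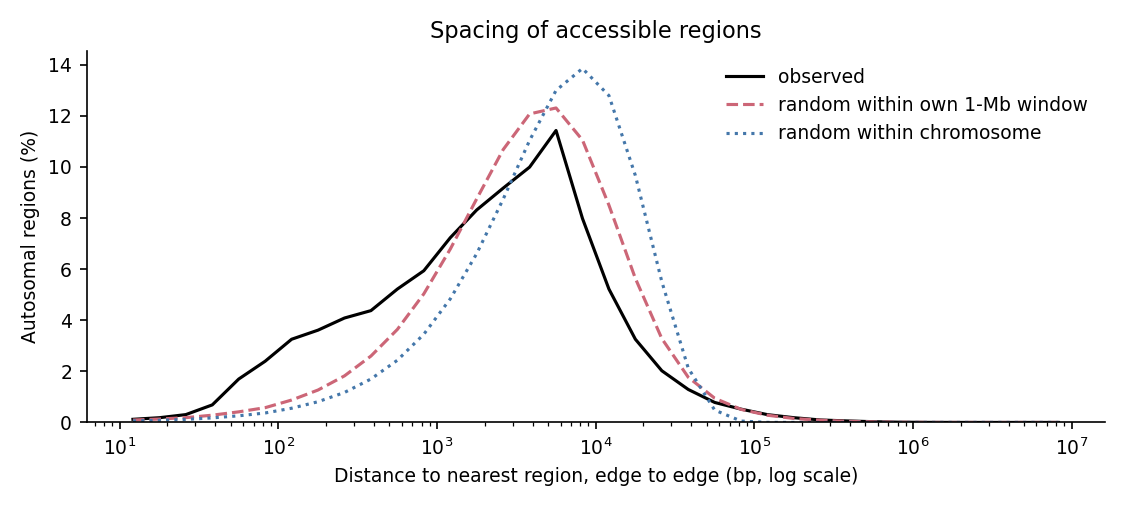
Percentage of autosomal regions (y axis) by distance to the nearest region, edge to edge (x axis, bp, log scale), as observed (black), with regions placed at random within their own 1-Mb window (red, dashed) and within their chromosome (blue, dotted). The observed curve is above both random curves at distances under 1 kb, where 32.1% of regions had a neighbour, against 17.2% within windows.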

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

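The 300 bp minimum and the joining were set beforehand for the catalogue of regions. All other settings, and the tests of the X, windows, spacing, wide regions and gaps, were chosen after seeing the data. For the density of the X, window counts, spacing and wide regions, every permutation p under these settings was the smallest its test allows. Only the values therefore show how far these results moved. The gap step was not compared with permutations under the alternatives. The adjusted value of the X, 0.063 in the list as deposited, was not computed under the alternatives. With regions of at least 300 bp alone, 108220 regions remained, and with regions under 500 bp apart joined, 133653. Over these settings and the list without regions of exactly 200 bp, the X to autosome density ratio ranged from 0.260 to 0.280. The variance to mean ratio of 1-Mb counts ranged from 26.0 to 32.8 over the same settings, and was 21.1 in windows of 500 kb and 50.1 in windows of 2 Mb. Random placements gave 0.882 to 1.01 in windows of 500 kb and 0.846 to 1.07 in windows of 2 Mb. For crowded regions this ratio depends on the mean count per window, which changes with window length and the number of regions kept. Its values are therefore not directly comparable between settings. The share of regions with a neighbour within 1 kb moved from 32.1% to 23.1% at 300 bp and to 13.1% after joining, which removes close neighbours by construction. The mean share in random placements on the same chromosome moved as well, from 11.3% to 8.25% at 300 bp and to 10.1% after joining. For neighbours within 500 bp the observed share was 21.9% against a random mean of 5.84%, and within 2 kb it was 46.0% against 21.3%. The wide to narrower ratio of nearest distances fell from 1.99 to 1.55 at 300 bp and to 1.34 after joining. The quotient of the changes in gap counts near 5 kb, beside wide over between narrow regions, was 1.87 at 300 bp (95% interval 1.68 to 2.08), 1.53 after joining (1.41 to 1.66) and 1.79 without regions of exactly 200 bp (1.63 to 1.97). The classes compared were not the same sets in each setting. Joined regions can reach 1 kb by being joined. The median width that bounds the narrow class was 497 bp at 300 bp, 441 bp after joining and 412 bp without regions of exactly 200 bp. Restriction to assembled chromosomes changed nothing, since the list names no other sequence. The alternatives set beforehand for changed regions, gene locations, gene lists and motifs, leaving out replicates included, were not run, because the list has no value per library and no rn6 annotation or sequence was used. No paired analysis was possible because the list has no value per library. The unknown depth limits what the list can show: regions missing from it may be closed or merely below the caller's threshold, and a lower width threshold than 200 bp (regions listed: 144302 without those at 200 bp) could not be tried.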

Other observations

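The 3 patterns weighed here were noticed in the list and then tested on the same list, so any explanation is a hypothesis. Except for the placements of joined regions at least 500 bp apart, the tests were chosen after the patterns were seen but before the values that decide them. The bounds of the gap step were set after the step in all gaps had been seen and before gaps were divided by the width of their flanks. The placements of joined regions at least 500 bp apart were added after the share of joined regions and its freely placed counterpart had been seen.

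No relation between density and chromosome length was detected on the autosomes. Across the 20 autosomes density and span had a Pearson r of -0.35 (permutation p = 0.13) and a Spearman rho of -0.23 (permutation p = 0.32), and without chromosomes 1 and 2 the r was -0.34 (permutation p = 0.17). Chromosome 17, with 64.6 regions per Mb, was denser than chromosome 11, with 47.2, although their spans were almost equal at 90.8 and 90.1 Mb. The shortest autosomes, 12, 20 and 19, were nonetheless dense, with 74.2, 72.3 and 71.3 regions per Mb. Chromosome 18, the next shortest, had 52.4, and chromosome 10, the densest, had a span of 112 Mb.

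The X chromosome held 0.276 times the autosomal density of regions. Long empty stretches were not the whole reason: counting only the windows with at least 1 region, the X had 17.8 ± 1.5 regions per window (SE over windows) against 45.4 ± 2.4 on chromosome 2, the lowest autosome. Male animals have a single X, and fewer reads on the X may leave more of its regions below a caller's threshold; the 21 regions on the Y go with males among the libraries, although reads from similar X sequence can also be placed there. The widths were mixed, since the share of X regions of 1 kb or more, 8.53%, and the share at the minimum width lay within the autosomal ranges, while the median of 371 bp was below the lowest autosomal median of 387 bp, and fewer reads cannot be told apart from a less accessible X without reads per chromosome. Fewer genes on the X, inactivation of an X in females and repeats that take no reads stay open and were not tested.

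Regions crowded together in the genome at both long and short range. Splitting of single sites into parts less than 500 bp apart does not account for the long-range part. Joining such parts left 133653 of 151302 regions, and the variance to mean ratio was still 28.6. With so few regions joined, the ratio could not have fallen to the range of random placements, so this value adds little to the count itself. Nor does such splitting account for all of the short-range part when the spacing is matched. Of joined regions 13.1% had a neighbour within 1 kb, against at most 8.63% in placements within windows at least 500 bp apart. Free placements within windows, which allow gaps shorter than joined regions can have, gave more, at 14.8% to 15.5%. Broad gradients alone do not account for the short-range part either, since 32.1% of autosomal regions in the list as deposited had a neighbour within 1 kb and at most 17.5% did when placed within their own windows. Clusters of promoters and enhancers around active genes are a candidate explanation that was not tested, and gradients finer than 1 Mb and sites listed in parts for the pairs under 500 bp apart stay open.

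Regions of 1 kb or more were in richer megabases and yet farther from their nearest neighbour at the median. Close neighbours taken into the wide regions by calling or merging were not the whole cause, since among regions with no neighbour within 1 kb the wide ones still had a median distance of 5773 bp, against 4393 bp for narrower ones and at most 4715 bp in permutations. A candidate explanation is a peak caller that takes its background from some kb around each position, so that a strong region hides weak ones nearby. It predicts a rise in the gap counts that is larger beside wide regions. Near 5 kb the count changed 1.65 times there and 0.935 times between narrow regions, a quotient of 1.77 (95% interval 1.61 to 1.94). Any cause that leaves fewer regions within some kb of wide ones can raise this quotient, and permuting widths removes that difference in distance. The quotient therefore partly restates the pattern and cannot tell such a caller from strong elements that are isolated in the genome. Hiding would also deplete the closest neighbours, and gaps under 250 bp were only slightly fewer beside wide regions, at 6.51% of gaps against 7.11% between narrow ones, a much weaker depletion than at 1000 to 1249 bp, with 1.46% against 2.80%. The caller is not given in the sources used here, width stands in for signal, and strong elements that are isolated in the genome stay open and were not tested.

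Widths at the lower end were not smooth. Exactly 200 bp was the width of 7000 regions, 4.63% of the list, while widths of 201 to 220 bp each had 306 to 653 regions, with a median of 384.5. The highest of these was at 209 bp, with 653 regions, or 1.70 times that median, and 205 bp followed with 495. The list had no region narrower than 200 bp.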
